A study of Homo sapiens with 2 samples.

How the data were processed

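RNA recovered from 2 pull-downs in U2OS cells, a human osteosarcoma line, was measured: 1 library labelled ZAK-alpha-RBR and 1 mock library. Per the labels' protocols, RNA was extracted from the pull-down with phenol-type reagents and ethanol precipitation, and adaptors were joined to the fragmented RNA by an engineered tRNA ligase from Arabidopsis, which seals a cyclic phosphate at the 3' end to a 5' phosphate. The libraries were sequenced on the Ion Proton, per the labels' protocols. The submitters' processing notes name cutadapt 2.0, a trimmer of adaptor sequence, and Bowtie2 2.3.4.1, a read aligner, without saying which settings were used. The reference sequence, the strand handling, the treatment of reads that map to several places and the removal of duplicate reads are not given in the sources used here.

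The deposited table lists every position of 18S rRNA (1870 positions) and 28S rRNA (5070 positions) with its base and, per the file headers, the normalized reads of each library. Both columns are a coverage signal as deposited: a read adds to every position it spans, so neighbouring positions share reads. The deposited signal sums to 78749474 in each column, so the authors scaled the ZAK-alpha-RBR library to the total of the mock. All mock values were whole numbers, and 100% of the ZAK-alpha-RBR values were whole multiples of 11.5 (tolerance 0.001 of a read), which gives the unscaled read depth at each position. Before scaling, the coverage summed to 6835941 in the ZAK-alpha-RBR library and 78749474 in the mock. The median read depth per position was 770.5 and 9865.5, so the ZAK-alpha-RBR values carry the larger counting error. The total number of reads is not known. The reads over the deepest positions of 18S and 28S must be different reads, which gives at least 17111 reads in the ZAK-alpha-RBR library and 98906 in the mock. Positions are counted from 1 at the 5' end of each rRNA, as in the deposited table. The rRNA genes are present in many copies, so no chromosome position is given.

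Each value was divided by its library's summed coverage and expressed in parts per 1000000 (ppm). Ratios are ZAK-alpha-RBR over mock on the log2 scale after adding a pseudocount of 1 ppm to both values, which understates the change at low coverage. Folds printed for a single position carry no pseudocount, while counts and runs of positions at a 2-fold or 4-fold limit use the ratio with it. With 1 library per group no spread between replicates exists, no test between groups was made, and no p-value is given. Exact Poisson intervals of read depths, exact binomial (Clopper-Pearson) intervals of shares and of the ratio of 2 depths are at 95%. They cover the counting error of reads only, and no spread between libraries. Reads without molecular identifiers can be copies of the same molecule, so for molecules these intervals may be too narrow by an unknown amount. The interval of the difference in fragment ends comes from a bootstrap over blocks of 100 positions and holds no spread between libraries either.

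These rules were set before the data were examined. A region was called higher or lower where the ratio, after both profiles were averaged over a centred window of 15 positions, was at least 2-fold above or below the median ratio of the same molecule over at least 10 positions in a row. The regions named are the 12 higher regions with the highest peak ratio and the 5 lower regions with the lowest. The peak is the position where the averaged ratio was most extreme. The fold printed for it is that of the single position, and other single positions can differ more. The 5 positions with the highest value in each library are named as well. There are also 6 landmark segments, found by exact match of their sequence in the table: 5 on 18S and 1 on 28S. Each landmark's ratio was ranked among 10000 randomly placed segments of the same length on the same molecule that did not overlap it, and again among placements whose mean level lay within 2-fold of its own, where at least 50 existed. The gene lists that had been set for a table of genes had no values here. On libraries simulated from the mock profile at the depths of this comparison (6940 positions), the region rule called 0 regions when nothing was changed. It found 1 of 20 planted segments changed 2-fold, 20 of 20 changed 3-fold and 20 of 20 changed 4-fold. All planted segments had the same length, longer than most of the named regions, and all simulated fragments had the same length. These counts therefore do not say how often shorter regions are found. Both simulated libraries were drawn from the same profile, so they differ only by counting error and the planted changes. The 0 calls are therefore no rate of false calls between 2 separately made libraries.

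The alternatives tried were scaling by the median of ratios, by the trimmed mean of M values and within each molecule, other pseudocounts, minimum depths, other windows, folds and baselines, and wider landmark segments. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Other RNAs, such as 5S and 5.8S rRNA and mRNA, were not analysed here.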

Results

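ZAKα, the long isoform of the kinase MAP3K20, starts the ribotoxic stress response, in which stalled ribosomes activate stress kinases, and the series asks how it recognises such ribosomes. To find where on the ribosome a ZAKα construct labelled RBR lies, the RNA that came down with it was compared with RNA from a mock pull-down by CLIP-seq, the sequencing of RNA fragments recovered with a protein. Coverage was given for 18S rRNA, the RNA of the small ribosomal subunit, and 28S rRNA, the main RNA of the large subunit. There was 1 library of each kind and so no replicate check. The median read depth on 18S was 991 reads per position in the ZAK-alpha-RBR library and 11611.5 in the mock, and on 28S it was 702 and 8981.5. No read covered 4 of the 6940 positions in the ZAK-alpha-RBR library and 2 in the mock.

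The small subunit RNA took a slightly larger share of the ZAK-alpha-RBR library. 18S rRNA held 35.8% of its coverage (95% exact binomial interval 35.1 to 36.5) against 32.9% of the mock coverage (32.6 to 33.2). 28S rRNA held 64.2% and 67.1%. The difference in the 18S share was smaller than the excess in the single region around helix 14, which held 4.70% of the ZAK-alpha-RBR coverage and 1.14% of the mock coverage. The intervals rest on the smallest possible number of reads.

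The highest peak of the ZAK-alpha-RBR library lay in 18S rRNA, over the segment that holds helix 14, a short hairpin of the small subunit body. This segment, CUACCACAUCCAAGGAAGGCAGCAG at positions 453 to 477, had a mean coverage of 1286 ppm in the ZAK-alpha-RBR library and 228 ppm in the mock, a log2 ratio of 2.49 (5.62-fold). It held 8.97% of all 18S coverage with ZAK-alpha-RBR and 1.73% with the mock. The 5 positions with the highest coverage in the whole ZAK-alpha-RBR library, 463, 465, 467, 469 and 471 of 18S, all lay inside it. The highest, G at position 471, was covered by 12973 reads (95% exact Poisson interval 12751 to 13198) against 22715 reads (22421 to 23012) in the mock, whose coverage was 11.5-fold deeper in total. After scaling this was a 6.58-fold difference (6.44 to 6.72), and at position 463 it was 7.44-fold (7.27 to 7.60).

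**Figure D1:**
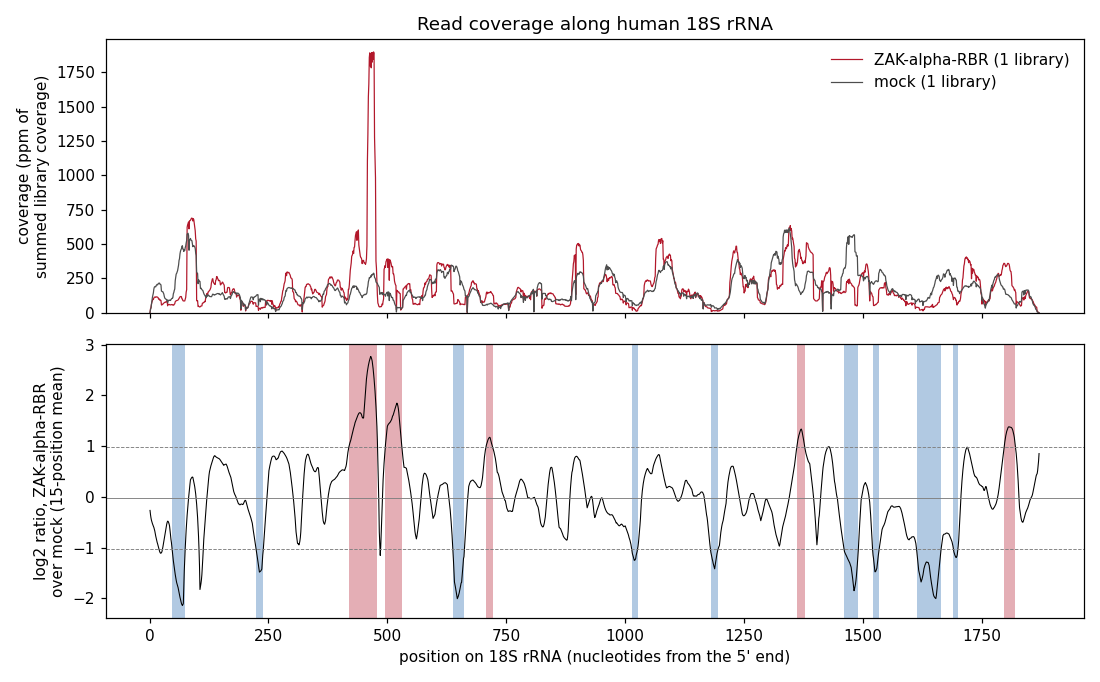
Read coverage along 18S rRNA (top; vertical axis, coverage in parts per 1000000, ppm, of the library's summed coverage) and the log2 ratio of ZAK-alpha-RBR over mock after averaging over 15 positions (bottom), both against the position from the 5' end; red and blue bands mark the higher and lower regions, and the lines mark the median ratio (solid) and 2-fold from it (dashed). The ZAK-alpha-RBR library reaches 1898 ppm at position 471, where the mock has 288 ppm.

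The ratio of the helix 14 segment was above that of all 10000 randomly placed segments of its length on 18S, and the highest placement elsewhere on 18S had a log2 ratio of 1.65. It was also above all of the 64 placements of similar mean level. That level is the mean of both libraries, so it includes the ZAK-alpha-RBR excess itself and does not match placements on the mock level. Placements overlap and share reads, so they are not separate comparisons. The ranks describe these 2 libraries and are no test of binding. The called region around the helix 14 segment spanned positions 419 to 479 (61 positions). It held 16.4% of all coverage by which ZAK-alpha-RBR exceeded the mock anywhere on the 2 rRNAs. Within it, the core, where coverage was above 50% of its peak, was ACAUCCAAGGAAGGCAGC, positions 458 to 475, where the means were 1638 and 254 ppm, 6.46-fold apart. The upstream shoulder, positions 419 to 457, was 2.77-fold higher with ZAK-alpha-RBR. Just downstream, at positions 480 to 495, the ZAK-alpha-RBR library was the lower one on average, with 109 against 152 ppm.

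**Figure D2:**
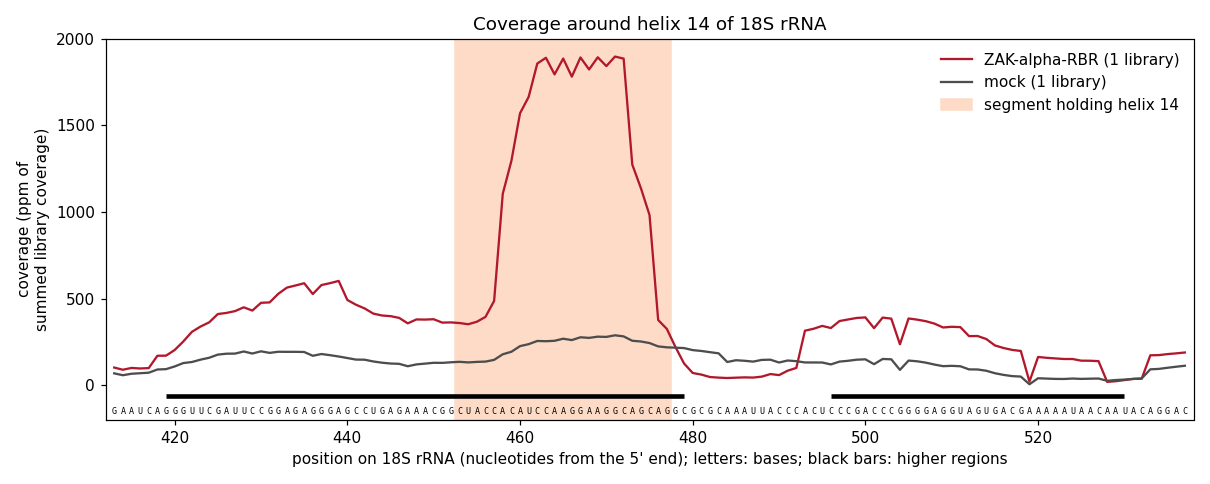
Coverage around helix 14 (vertical axis, coverage in parts per 1000000, ppm, of the library's summed coverage; horizontal axis, position on 18S rRNA with its bases); lines are the 2 libraries, the shaded band is the landmark segment at 453 to 477 and black bars are the higher regions. Coverage in the ZAK-alpha-RBR library steps up at position 458 and down after positions 472 and 475, while the mock reaches at most 288 ppm.

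At the other landmarks the log2 ratios lay between -0.82 and 0.24. The 530 loop in helix 18, part of the decoding site, at positions 611 to 633 had 342 ppm with ZAK-alpha-RBR and 290 with the mock, a log2 ratio of 0.24 at percentile 63.7 of random segments. The segment of helices 27 and 28 at positions 1194 to 1219 had a log2 ratio of -0.28 (percentile 29.2), and the 3' end of 18S at positions 1843 to 1869 had -0.0023 (percentile 50.2). The strand that leads into helix 44, the long helix of the decoding site, at positions 1691 to 1709 had 106 ppm against 188 in the mock, a log2 ratio of -0.82 (percentile 14.5). On 28S, the sarcin-ricin loop, the site that activates translation factors and that ribotoxins attack, at positions 4598 to 4615 had 246 against 406 ppm, a log2 ratio of -0.72 (percentile 11.6). The ratios of the helix 18 and of the helix 27 and 28 segments turned sign when the segments were widened by 10 positions on each side, and that of the helix 44 strand was then -0.18.

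Beyond helix 14, smaller excesses appeared on both rRNAs. The rule found 5 higher regions on 18S, with 151 positions in all, and 9 on 28S, with 177 positions. Closest to helix 14 was the region at 496 to 530 of 18S, 18 positions downstream of the segment, where position 520 was 4.04-fold higher (3.77 to 4.32) with ZAK-alpha-RBR. In the 18S region at 1797 to 1820, position 1807 was 2.84-fold higher (2.72 to 2.97), and in the region at 1361 to 1377, position 1370 was 2.86-fold higher (2.74 to 2.98). On 28S the largest were at 759 to 793, where position 769 was 5.75-fold higher (5.29 to 6.24), and at 1086 to 1110, where position 1098 was 5.42-fold higher (5.13 to 5.72). These 28S regions held little of the library, 0.403% and 0.518% of the ZAK-alpha-RBR coverage against 0.100% and 0.129% of the mock coverage. The region at 2117 to 2137 of 28S peaked at 3.45-fold (3.24 to 3.67) at position 2125. The other named regions of 28S, at 115 to 126, 492 to 514, 1627 to 1637, 3046 to 3066 and 3973 to 3982, were between 2.73-fold and 2.94-fold higher at their peaks. The 28S regions at 759 to 793, 2117 to 2137 and 3046 to 3066 consist largely of short repeats. How reads that map to several places were treated is not known, and the intervals do not cover errors of placement. At a limit of 3-fold above the median, 4 of the 12 named regions, the one around helix 14 among them, were still called.

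Lower regions were more numerous, though on 28S the margin depended on the baseline: with library totals in place of the median ratio, 28S had 16 higher and 19 lower regions. By the rule there were 9 on 18S and 23 on 28S, which together took 5.04% of the ZAK-alpha-RBR coverage and 14.8% of the mock coverage. The lowest ratio of either rRNA after averaging over 15 positions was on 28S, at 2342 to 2379. There position 2361, the low point of the averaged ratio, was 8.18-fold lower (7.27 to 9.25) with ZAK-alpha-RBR, at 276 reads against 26013. In the 28S region at 3858 to 3886, position 3863 was 5.83-fold lower (5.18 to 6.59), and in the region at 2417 to 2433, position 2426 was 4.81-fold lower (4.24 to 5.48). The last 65 positions of 28S, 5006 to 5070, formed 1 lower region with 62.6 against 201 ppm, and near the 5' end of 18S the region at 48 to 74 had 88.2 against 333 ppm. The smoothed log2 ratio in the 28S region at 2342 to 2379 reached -3.04, farther from 0 than the 2.77 of the region around helix 14, and the next lowest region, at 3858 to 3886, reached -2.24. In absolute coverage the difference was larger at helix 14: the widest gap at a single position was 1636 ppm, at position 463 of 18S, and the widest gap in favour of the mock was 388 ppm, at position 1483 of 18S. The 32 lower regions were poorer in G and C (48.0% of bases) than the rRNAs as a whole (56.0% of 18S and 69.3% of 28S), and they held 62 places where a C is followed by an A, against a median of 25 in regions of the same lengths placed at random. With averaging over 31 positions the log2 ratios at the peaks were -0.94 at 2417 to 2433, which was then no longer called, -1.05 at 3858 to 3886 and -1.06 at 48 to 74 of 18S.

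**Figure D3:**
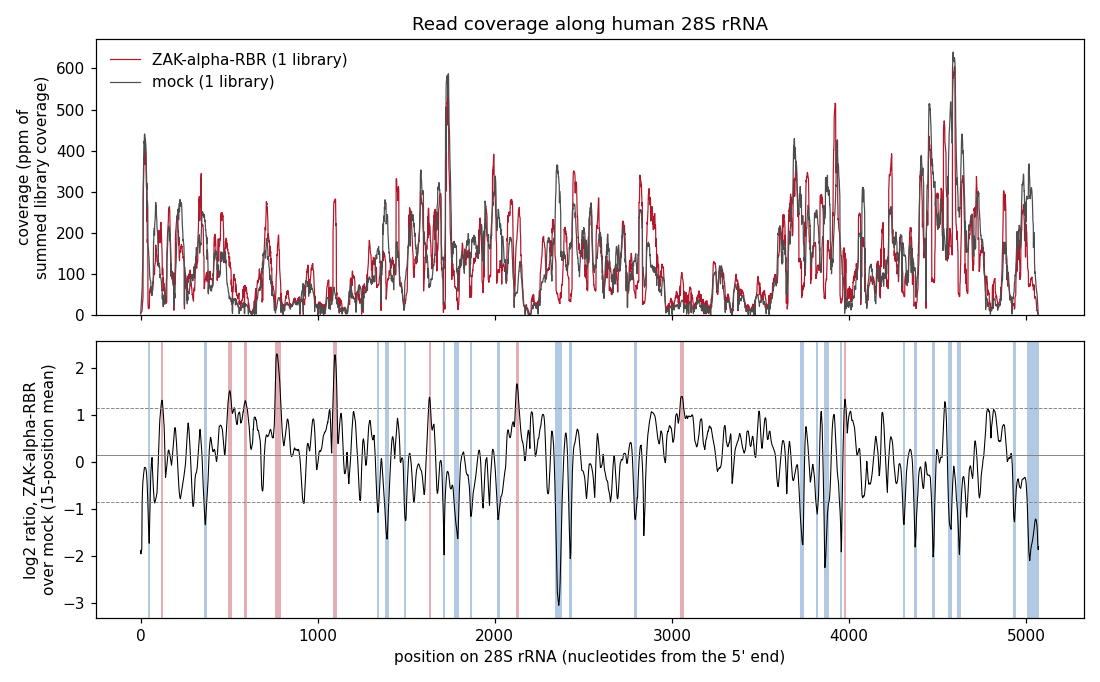
Read coverage along 28S rRNA (top; vertical axis, coverage in parts per 1000000, ppm, of the library's summed coverage) and the log2 ratio of ZAK-alpha-RBR over mock after averaging over 15 positions (bottom), both against the position from the 5' end; bands and lines are as for 18S. The highest value, in the mock, is 640 ppm, and the lower regions called against the median ratio (23) outnumber the higher ones (9).

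Of the 6940 positions, 5465 lay within 2-fold of each other in the 2 libraries, 646 were at least 2-fold higher with ZAK-alpha-RBR and 829 at least 2-fold lower. Scaling by the median of ratios gave 489 higher and 965 lower, scaling within each molecule 715 and 849, and library totals without the highest 18S region, an alternative chosen after seeing the data, 737 and 791. A pseudocount of 10 ppm gave 422 and 731. On 28S, 90% of the log2 ratios lay between -1.56 and 1.16, and on 18S between -1.70 and 1.35. The log2 coverages of the 2 libraries correlated with r = 0.81 across the positions of 28S and r = 0.68 across those of 18S, and neighbouring positions share reads and are not independent. The highest positions of the mock library were on 28S, at 4586, 4587, 4588, 4590 and 4591, a short way upstream of the sarcin-ricin loop. There the ZAK-alpha-RBR library was at a similar level: position 4588 had 640 ppm in the mock and 588 with ZAK-alpha-RBR, a fold of 0.918 (0.889 to 0.948). With the pseudocount of 1 ppm, 52 positions were at least 4-fold higher with ZAK-alpha-RBR and 177 were at least 4-fold lower. Among the higher ones the longest run was 458 to 475 of 18S. The other runs were at 521 to 523 of 18S and at 557, 764 to 780 and 1093 to 1105 of 28S.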

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

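The alternatives with totals that leave out the highest 18S region, with regions of at least 20 positions and with filled homopolymer dips were chosen after seeing the data. The excess at the helix 14 segment kept its direction, and its log2 ratio of 2.49 was 2.37 with scaling within each molecule, 2.45 with a pseudocount of 10 ppm and 2.07 with the segment widened by 10 positions on each side. Widening gave -0.10 for the 530 loop, 0.25 for helices 27 and 28, -0.18 for the helix 44 strand, -0.18 for the 18S 3' end and -0.56 for the sarcin-ricin loop, and scaling within each molecule gave 0.11 for the 530 loop and -0.12 for the 18S 3' end. Scaling within each molecule also moved the median log2 ratio of 18S from -0.02 to -0.14 and that of 28S from 0.15 to 0.21. The number of regions depends on the rule, by its construction. A window of 31 positions left 3 higher regions on 18S and 4 lower regions on 18S and 11 on 28S. A 3-fold limit left 3 higher and 3 lower regions on 18S, and 2 higher and 7 lower on 28S, and a 1.5-fold limit gave 12 higher on 18S and 32 higher and 46 lower on 28S. Library totals as the baseline gave 16 higher and 19 lower regions on 28S. Regions of at least 20 positions numbered 3 higher and 4 lower on 18S, and 5 higher and 8 lower on 28S. Of the 12 named higher regions, 4 were found again at the 3-fold limit, 8 each with the window of 31 positions and with regions of at least 20, 10 each with only positions above the lower quartile of mean coverage and with a pseudocount of 10 ppm, and all 12 with the window of 5 positions, the 1.5-fold limit, library totals as the baseline and filled dips. The window of 31 positions found 4 of the 5 named lower regions again, lost the one at 2417 to 2433 of 28S (-0.94) and reduced 3858 to 3886 of 28S to -1.05 and 48 to 74 of 18S to -1.06. Regions of at least 20 positions also lost 2417 to 2433, and the other settings found all 5. No named region changed sign at its peak under these settings. A pseudocount of 10 ppm gave 422 positions at least 2-fold higher, and totals without the highest 18S region 737 higher and 791 lower. Without the 10 positions of highest coverage, 18S held 34.6% of the ZAK-alpha-RBR coverage and 32.7% of the mock coverage. With 1 library per group no replicate could be left out, and the alternatives for gene lists were not run because the table lists no genes. On simulated libraries of these depths the region rule found 1 of 20 segments changed 2-fold, which is the limit of the rule itself, and 20 of 20 changed 3-fold. Other depths, other lengths of segments or fragments and the spread between separately made libraries were not simulated.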

Other observations

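The tests of unevenness between the libraries, of segments between C-A steps, of GC content as the whole cause and of homopolymers were chosen after the result was seen. Several regions lie within 20 positions of a landmark or catalytic site. These distances were looked up after the regions were known, and whether 46 regions would lie as close by chance was not tested. The 18S region at 1797 to 1820 is separated by 3 positions from the adenine at position 1824 that monitors codon pairing in the decoding site. Among the lower regions of 18S, 638 to 662 is separated by 4 positions from the 530 loop, 1180 to 1195 overlaps the segment of helices 27 and 28, and 1690 to 1699 overlaps the strand that leads into helix 44. On 28S, the lower region at 4367 to 4384 lies 12 positions upstream of the peptidyl transferase adenine at position 4397. The lower region at 4609 to 4632 overlaps the sarcin-ricin loop, and the one at 4561 to 4580 lies 17 positions upstream of it.

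The ends of the fragments differed between the libraries. With dips at runs of equal bases filled, 53.3% of the falls in ZAK-alpha-RBR coverage came after a C, against 39.2% in the mock, and 19.2% against 31.1% came after a G. The step from C to A makes up 3.69% of neighbouring bases, yet it held 26.7% of the falls and 28.4% of the rises in the ZAK-alpha-RBR library, against 14.4% and 18.5% in the mock. A fall marks the 3' end of reads and a rise the 5' start, so both ends lay more often at this step in the ZAK-alpha-RBR library.

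The peak at helix 14 is bounded by such steps, with 32.6% of its height gained at the rise into position 458 and 32.2% lost at the fall after position 472, which raises the question of whether it is made by the way the RNA was cut or amplified. A single amplified fragment that made the whole peak would need nearly the whole height at each edge, and the smaller of these shares was 0.322. Depth also fell from 6716 reads at position 475 to 2575 at position 476. Whether a few amplified fragments together make most of the peak was not tested, so amplification stays open. Whether cutting at the steps on both edges makes the peak cannot be told. The 165 other segments of 10 to 25 positions between 2 such steps had a median log2 ratio of -0.73, but cutting at these steps may lower coverage as well as raise it, and the segment at 458 to 472, with 2.77, holds the highest smoothed ratio of either rRNA, so this comparison decides nothing. Unevenness between single libraries stays open: 12 of 5046 overlapping segments of 25 positions on 28S had an absolute log2 ratio at least as large as the 2.49 of the segment at 453 to 477. All were shifted copies of 1 place, inside the lower region at 2342 to 2379, and without replicates this cannot be told apart from contact of the protein with helix 14. Protection of helix 14 by the bound protein is a hypothesis that was not tested.

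The 32 lower regions may reflect cutting of the RNA. They contain 62 steps from C to A, against a median of 25 and a middle 95% of 16 to 35 in regions of the same lengths placed at random on the same rRNA, and the share of falls after C was 14.2 percentage points higher in the ZAK-alpha-RBR library (95% interval 10.5 to 17.8 from resampling blocks of 100 positions of the same 2 libraries, which holds no spread between libraries; 10.8 points without filling). Their GC content, 48.0%, was also below the 59.1 to 71.7% of random placements, and the parts of GC content and of C-A steps were not separated. C-A steps were not counted in the higher regions, and the region around helix 14 holds several of them, so such steps do not go with lower coverage alone. Median log2 ratios rose from -0.43 in the class of lowest GC content to 0.39 in the highest on 18S, and from -0.43 to 0.55 on 28S. Removing the median ratio of positions of like GC content left 18 of the 32 lower regions and 9 of the 14 higher ones. The log2 ratio at position 465 in helix 14 was then 2.66. These class medians thus do not account in full for the 18 lower regions left. GC content was counted over 31 positions only, and other widths were not tried, so GC content as a cause stays open. A different amount or kind of nuclease digestion is a candidate explanation, since the labels do not say how the RNA was fragmented, and no biological explanation was tested.

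Single positions with a deep dip occur in both libraries, for example at position 519 of 18S, the first of 5 adenines, where the depth was 0.117 of that of its neighbours with ZAK-alpha-RBR and 0.126 in the mock. The median relative depth at the first base of runs of at least 4 equal bases was 0.565 in the ZAK-alpha-RBR library (188 runs) and 0.585 in the mock (190 runs), against 1.01 at single bases in both and 1.006 and 1.002 at the last base of the same runs. This is consistent with errors in the length of homopolymers, which semiconductor sequencing is known for, aligned as gaps at the first base. The dips fall alike in both libraries and filling them left the count of regions at 5 and 9 higher and 9 and 23 lower, but a profile of one library read position by position could take them for protein or modification sites.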
